A study of Mus musculus with 54 samples.

How the data were processed

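Messenger RNA of liver and adipose tissue was sequenced from 27 male C57BL/6J mice kept for 16 weeks on 1 of 3 diets, with 9 mice per diet and 54 libraries in all. The groups and replicate numbers were taken from the sample titles. RNA was extracted with TRIZOL and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36, checked with FastQC 0.11.4 and aligned with HISAT2 2.0.5 to GRCm38, per the submitters' processing notes. The authors deposited, for each library, raw counts per gene, made with featureCounts 1.5.1, which counted fragments over exons with strand option 2 (reverse stranded), per the file headers. Option 2 matches a kit of this kind, so a gene and its antisense partner were counted apart. The annotation release is not given in the sources used here.

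The counts were used as deposited. The tables list 49671 genes by Ensembl identifier with coordinates. Symbols were taken from a table of gene names, which held 49326 of the identifiers, and gene positions are those of the deposited tables (GRCm38). No pair of libraries of a group held identical values or differed by as little as sampling noise: the lowest chi-square per gene was 5.33. Whether the liver and the adipose library with the same number came from the same mouse is not stated, so the interaction test does not pair them. The p-values rest on 9 libraries per diet, described in the labels as 9 mice, and a p-value over them measures the spread between mice of this experiment.

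Each tissue was fitted over its 27 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15, large group size 10, minimum proportion 0.7), which left 13591 genes in liver and 16645 in adipose tissue. TMM normalisation, robust dispersion estimates and the quasi-likelihood F-test followed, with Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p below 0.05 are those called, and "rose" and "fell" are used of these. The comparisons were HFD vs ND, ALL vs HFD and ALL vs ND in each tissue. A joint fit of the 54 libraries over 17414 genes tested whether the diet effect differed between tissues, as an interaction. Genes called in HFD vs ND and in the opposite direction in ALL vs HFD were counted. Because both comparisons share the HFD libraries, that count was set beside 20 simulations with no effect, beside independent lists of the same sizes and beside a split of the HFD libraries. Levels are CPM, counts scaled to the library size. An SD after a level and an SE after a log2 fold change are over 9 libraries per diet, and adjusted p-values of genes are those of edgeR unless another tool is named. Counting intervals cover counting error only.

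Gene lists were tested with camera from limma 3.58.1, which compares the members with all other genes, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Its p-values were adjusted over the lists run in that tissue, 25 in each, out of 30 lists fixed. A list needed 3 tested members. In liver the muscle and pancreas markers had 1 tested member and were not run. Member counts are given over all genes tested and "adjusted over the list alone". A further 6 lists were added after the data had been seen: duct epithelium, motile cilia, spermatids, epididymal head, nuclear RNA and glucocorticoid response. They are reported as mean log2 CPM with a prior count of 2, and differences in such means were tested by exact permutation over 48620 resamples, two-sided, as a family of 39 tests with Benjamini-Hochberg adjustment.

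The groups, comparisons, tests, 30 gene lists, 83 other settings of the processing and the rule for named genes were fixed before the data were examined. The rule names a preset set of genes and up to 3 called members with the smallest p of each list, or the member with the smallest p where none was called. It also names the 5 rises and 5 falls with the largest log2 fold change in HFD vs ND and in ALL vs HFD, and 3 of each in ALL vs ND and in the tissue differences. These last needed an adjusted p below 0.05, a mean of at least 1 CPM and, within a tissue, at least 8 of 9 libraries beyond the other diet's median. Predicted genes and pseudogenes were left out of this last part. The genes taken from this rule for the text make 195 gene and comparison pairs, and some genes that it names are not reported here. Other list members are named without values, after these were seen, only to say what a list's called members do. Ucp1, a preset gene, did not pass the filter in adipose tissue and was not tested.

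The gene tests were tried on simulated data made from the real means, dispersions and library sizes with 200 genes changed. At a 2-fold change the liver comparisons recovered 88 to 91% of them (HFD vs ND 88, ALL vs HFD 89.5, ALL vs ND 91) and the adipose comparisons 75 to 77% (75.5, 77 and 75). The tissue difference recovered 63.5% in HFD vs ND and 58.5% in ALL vs HFD. The common biological coefficient of variation was 0.213 in liver and 0.443 in adipose tissue.

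The other settings fixed then were DESeq2 1.42.0, limma-voom with sample quality weights, DESeq2-type size factors in edgeR, no filter on low counts, a filter of 1 CPM in at least 9 libraries, the 2 diets of a comparison alone, the replicate number as a block (for tissue differences in limma-voom, as a correlation within diet and number), each library left out in turn and a log2 fold change of at least 1. After the data had been seen, fits were added without 5 adipose libraries that held transcripts of other organs (ND 1, 2, 8 and 9 and HFD 7), with the duct epithelium mean as a covariate, with both, and without 3 liver libraries that stood apart on the second principal component (ND 7, HFD 1 and ALL 8). Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Body weight, serum and histology are not analysed here.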

Results

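Liver and adipose tissue were taken from 27 male mice of the inbred strain C57BL/6J that had received 1 of 3 diets for 16 weeks. A normal diet (ND), a high-fat diet with 20% fat and 1% cholesterol (HFD), and the same high-fat diet with 5% D-allulose (ALL) were given to 9 mice each. D-allulose is a rare sugar, an epimer of fructose. Polyadenylated RNA was sequenced from both tissues, which gave 54 libraries in 6 groups of 9. Total counts per library were 10723718 to 14938966 in liver (n = 27) and 11991206 to 15273244 in adipose tissue (n = 27). HFD vs ND asks what the high-fat, high-cholesterol diet did, ALL vs HFD what D-allulose did on that diet, and ALL vs ND how far the D-allulose group lay from the normal diet.

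The liver of HFD mice carried lower transcripts of cholesterol synthesis and higher transcripts of macrophages, inflammation, fibrosis and cell division than the liver of ND mice, though fibrosis and the cell cycle were not called with an estimated correlation. Sqle, which encodes squalene epoxidase of the sterol pathway, fell from 14.2 ± 11.2 to 0.83 ± 0.41 CPM, a log2 fold change of −4.09 ± 0.38 (adjusted p = 5.6e-09). Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.378 ± 0.426 to 22.4 ± 11.1 CPM, by 5.76 ± 0.52 on the log2 scale (adjusted p = 6.7e-09). In this comparison 3847 of 13591 genes were called, 2140 higher and 1707 lower in HFD. The deposited tables place Sqle (ENSMUSG00000022351) on chromosome 15 from 59315077 to 59331192 and Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929.

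Of 23 members of the cholesterol synthesis and uptake list, 22 fell and 1 was not called (22 lower adjusted over the list alone). The list's median log2 fold change was −1.15 (adjusted p = 1.31e-19, and adjusted p = 0.0408 with an estimated correlation). Idi1, Cyp51 and Tm7sf2, enzymes of sterol synthesis, fell by 3.42, 2.36 and 2.31 on the log2 scale. Among 19 genes of fatty acid and triglyceride synthesis, 3 rose and 6 fell (3 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.0664). The members that fell include Fads1, Fads2 and Elovl5, which act on polyunsaturated fatty acids, and Acacb, whose product restrains mitochondrial fatty acid import (log2 fold change −1.64 ± 0.21). Srebf1, a transcription factor of lipid synthesis, rose by 0.82 ± 0.21. The values of Fasn, fatty acid synthase, and of the desaturase Scd1 were 0.28 ± 0.20 (adjusted p = 0.33) and 0.35 ± 0.20 (adjusted p = 0.2). Fasn passed with limma-voom at 0.46 (adjusted p = 0.039).

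Among 18 lipid droplet and lipid uptake genes, 8 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.00523, and adjusted p = 0.274 with an estimated correlation). Cidea, a lipid droplet protein, rose from 1.87 ± 2.9 to 47.2 ± 14.3 CPM. Cidec, of the same family, rose by 1.34 ± 0.29, the lipase Lpl by 2.76 ± 0.18, the lipoprotein receptor Vldlr by 1.53 ± 0.14 and the fatty acid carrier Fabp4 by 2.30 ± 0.26. Cd36, a fatty acid transporter, rose by 0.58 ± 0.19 (adjusted p = 0.021), which did not pass without a filter on low counts (adjusted p = 0.063). The members that fell were G0s2 and Mgll, which act in lipolysis. Of 23 fatty acid oxidation and ketogenesis genes 10 fell (13 adjusted over the list alone), with a median of −0.26 (adjusted p = 5.21e-05, and adjusted p = 0.255 with an estimated correlation). The fatty acid hydroxylase Cyp4a14 fell by 1.51 on the log2 scale, while Ppara, the regulator of this pathway, had a value of 0.01 ± 0.16 (adjusted p = 0.97). Oxidative phosphorylation genes fell in 17 of 22 cases (19 adjusted over the list alone), with a median of −0.39 (adjusted p = 7.9e-08, and adjusted p = 0.239 with an estimated correlation), among them Ndufb5 at −0.44 ± 0.08.

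Bile acid synthesis and sterol transport genes went both ways, 5 higher and 5 lower of 19 (5 and 6 adjusted over the list alone), with a median of −0.04, a mean of 0.06 and no call (adjusted p = 0.882). Abcg5, a sterol exporter subunit gene, rose by 1.26 ± 0.11 and Slc10a1, the bile acid importer, fell by 1.09 on the log2 scale. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a value of −0.31 ± 0.28 (adjusted p = 0.43). Sugar metabolism genes were 1 higher and 8 lower of 17 (3 and 8 adjusted over the list alone), with a median of −0.36 (adjusted p = 0.00854, and adjusted p = 0.206 with an estimated correlation). The members that fell include the gluconeogenic enzymes G6pc (−1.16 ± 0.19) and Pck1 (−0.87 ± 0.15) and enzymes of fructose use. Khk, ketohexokinase, was −0.38 ± 0.13 (adjusted p = 0.022), and this call ended without ND 7 (−0.30, adjusted p = 0.058).

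Inflammatory cytokine and receptor genes rose in 21 of 22 cases (21 adjusted over the list alone), with a median of 1.64 (adjusted p = 1.05e-15, and adjusted p = 0.0239 with an estimated correlation). Ccl2, a monocyte chemoattractant, rose from 0.914 ± 0.423 to 5.07 ± 1.15 CPM. The adhesion molecule gene Icam1 rose by 1.69 ± 0.15 and the receptor gene Tlr2 by 1.82 ± 0.22. Of 21 macrophage markers 18 rose (19 adjusted over the list alone), with a median of 1.66 (adjusted p = 3.68e-19, and adjusted p = 0.0239 with an estimated correlation). Examples are Lgals3 at 2.95 ± 0.21, Clec7a at 2.47 ± 0.23, Lyz2 at 1.84 ± 0.17 and the macrophage elastase Mmp12 at 4.36 ± 0.40. Antigen presentation genes rose in 7 of 13 cases (7 adjusted over the list alone), with a median of 1.67 (adjusted p = 4.64e-05, and adjusted p = 0.274 with an estimated correlation). These were class II genes, such as H2-Aa at 1.96 ± 0.27 and Cd74 at 1.92 ± 0.27. Interferon response genes were 4 higher and 1 lower of 15 (5 and 2 adjusted over the list alone, adjusted p = 0.526). Lymphocyte markers rose in 3 of 6 cases without a call of the list (adjusted p = 0.0516), which passed with DESeq2-type size factors (adjusted p = 0.0472) and without ND 7, HFD 1 and ALL 8 (adjusted p = 0.0178). The markers of neutrophils and mast cells rose in 2 of 3 cases (adjusted p = 0.0276, and adjusted p = 0.206 with an estimated correlation).

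Extracellular matrix genes rose in 17 of 20 cases (19 adjusted over the list alone), with a median of 0.92 (adjusted p = 2.76e-09, and adjusted p = 0.206 with an estimated correlation). Col3a1, a fibrillar collagen, rose by 1.78 ± 0.27 and the collagenase Mmp13 by 3.03 ± 0.48. Markers of stellate cells and cholangiocytes rose in 4 of 10 cases (6 adjusted over the list alone, adjusted p = 0.0276, and adjusted p = 0.292 with an estimated correlation). That call ended without ND 3 or without ND 5, where the adjusted p was at most 0.0532. Cell cycle genes rose in 11 of 13 cases (11 adjusted over the list alone), with a median of 1.19 (adjusted p = 5.21e-05, and adjusted p = 0.206 with an estimated correlation), among them Mki67 at 1.77 ± 0.28 and Top2a at 1.62 ± 0.28. Immediate early genes rose in 7 of 14 cases (7 adjusted over the list alone, median 0.60, adjusted p = 0.00561, and adjusted p = 0.274 with an estimated correlation). Endothelial markers, all 13 of which the ND liver expressed at 1 CPM or more, had 1 member higher and a median of 0.13 (adjusted p = 0.298).

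Xenobiotic metabolism genes were 8 higher and 1 lower of 18 (11 and 1 adjusted over the list alone), with a median of 0.47 (adjusted p = 0.00547, and adjusted p = 0.274 with an estimated correlation). The glutathione transferase genes Gsta1 and Gstm3 rose by 3.32 ± 0.47 and 2.74 ± 0.40. Of 12 male-predominant liver genes 1 rose and 6 fell (1 and 6 adjusted over the list alone), with a median of −0.73 (adjusted p = 0.00561, and adjusted p = 0.247 with an estimated correlation). The steroid dehydrogenase gene Hsd3b5 fell from 114 ± 85.3 to 5.15 ± 5.44 CPM, and the transporter gene Slco1a1 fell by 1.83 on the log2 scale. Female-predominant genes were 2 lower of 5, with a median of 0.47, a mean of −0.54 and no call (adjusted p = 0.215). One of those was Cyp17a1, of steroid synthesis, at −3.38 ± 0.28. No call was made for the lists of the circadian clock (1 of 16 lower, adjusted p = 0.372), endoplasmic reticulum stress (3 of 15 higher, adjusted p = 0.0613), adipocyte identity (3 higher and 1 lower of 10, adjusted p = 0.653) or erythroid cells (0 of 5, adjusted p = 0.215). Endoplasmic reticulum stress passed with the 2 diets fitted alone (adjusted p = 0.0378). Among the other largest changes, Sdcbp2, Orm3, Chrna4 and Tff3 had log2 fold changes of 4.96, 4.08, −5.19 and −3.87, each on the same side in 9 of 9 libraries. Orm3 encodes an acute-phase glycoprotein and Tff3 a mucosal trefoil peptide.

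**Figure D1:**
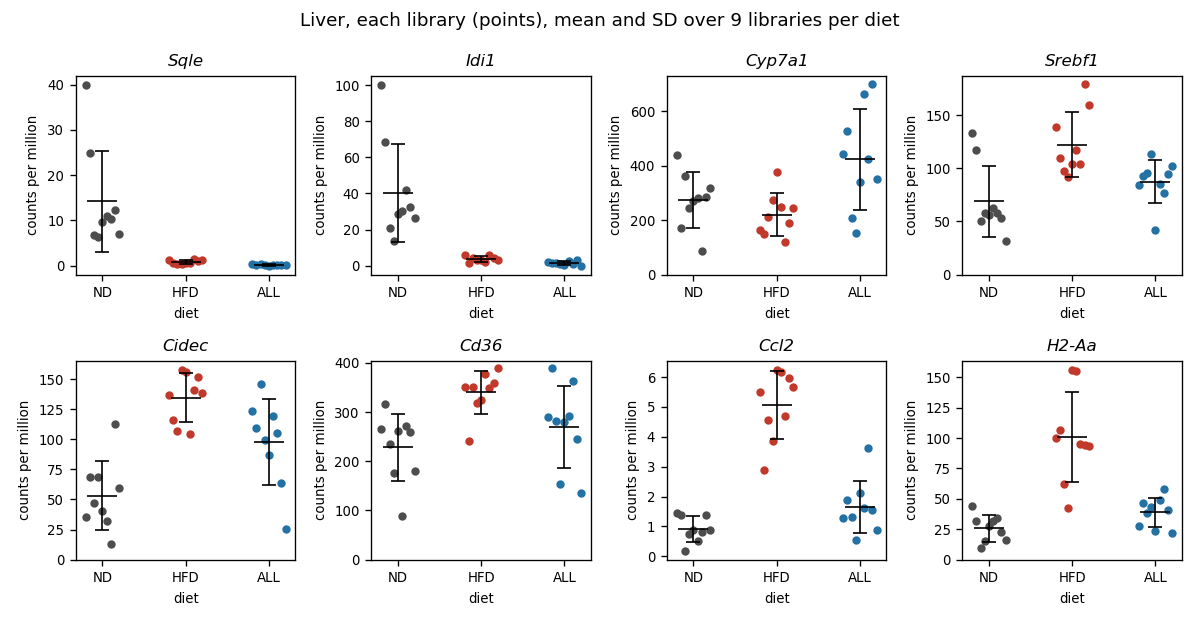
CPM per liver library (linear axes, 0 included) for 8 genes in ND, HFD and ALL, with points for the 9 libraries of each diet and bars for the mean ± SD. Sqle and Idi1 lie lower in HFD than in ND, and Ccl2 and H2-Aa lie higher in HFD than in either other diet.

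With D-allulose on the high-fat diet, the liver held fewer macrophage, inflammation, matrix and cell cycle transcripts than with the high-fat diet alone, and more transcripts of fatty acid oxidation and of male-predominant liver genes. With an estimated correlation only the male-predominant list was called. Ccl2 fell from 5.07 ± 1.15 to 1.65 ± 0.88 CPM (log2 fold change −1.61 ± 0.26, adjusted p = 5.3e-05), and Cyp7a1 rose from 220 ± 78.1 to 424 ± 186 CPM (0.94 ± 0.28, adjusted p = 0.016). The most negative change of a named gene was that of Slc39a4, a zinc transporter, which fell from 21.2 ± 6.43 to 1.84 ± 0.67 CPM (−3.52 ± 0.25, adjusted p = 2.2e-10). In ALL vs HFD 2799 genes were called in liver, 1080 higher and 1719 lower in ALL. Ccl2 (ENSMUSG00000035385) lies on chromosome 11 from 82035571 to 82037453, Cyp7a1 (ENSMUSG00000028240) on chromosome 4 from 6265612 to 6275633 and Slc39a4 (ENSMUSG00000063354) on chromosome 15 from 76612385 to 76616852.

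Inflammatory cytokine and receptor genes fell in 14 of 22 cases (14 adjusted over the list alone), with a median of −1.01 (adjusted p = 2.27e-08, and adjusted p = 0.154 with an estimated correlation). Icam1 fell by 0.93 on the log2 scale. Of 21 macrophage markers 17 fell (18 adjusted over the list alone), with a median of −0.92 (adjusted p = 6.52e-11, and adjusted p = 0.149 with an estimated correlation). Lgals3, Cd68 and the osteoclast-type proton pump gene Atp6v0d2 were at −1.54 ± 0.19, −0.92 ± 0.14 and −2.08 ± 0.26. Antigen presentation genes fell in 10 of 13 cases (11 adjusted over the list alone), with a median of −1.31 (adjusted p = 1.18e-06, and adjusted p = 0.246 with an estimated correlation), among them H2-Aa at −1.37 ± 0.26 and H2-DMb1 at −1.48 ± 0.23. Interferon response genes fell in 7 of 15 cases (8 adjusted over the list alone, median −0.46, adjusted p = 0.000261, and adjusted p = 0.251 with an estimated correlation), with Oas1a at −1.11 ± 0.17. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, and Tgtp1, an interferon-induced GTPase, fell by 2.87 and 3.08 on the log2 scale. Tgtp1 did not pass with limma-voom (adjusted p = 0.09).

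Extracellular matrix genes fell in 13 of 20 cases (17 adjusted over the list alone), with a median of −0.67 (adjusted p = 1.02e-06, and adjusted p = 0.246 with an estimated correlation), and Col3a1 fell from 66.8 ± 27.1 to 23.9 ± 6.63 CPM. Cell cycle genes fell in 7 of 13 cases (8 adjusted over the list alone), with a median of −0.78 (adjusted p = 0.000275, and adjusted p = 0.246 with an estimated correlation), with Mki67 at −1.46 ± 0.27 and Top2a at −1.27 ± 0.27. No call was made for stellate cells and cholangiocytes (2 of 10 lower, adjusted p = 0.0966), lymphocytes (2 of 6 lower, adjusted p = 0.162) or endothelial cells (0 of 13, adjusted p = 0.438).

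Fatty acid oxidation genes rose in 14 of 23 cases (15 adjusted over the list alone), with a median of 0.24 (adjusted p = 1.02e-06, and adjusted p = 0.246 with an estimated correlation). Cyp4a14 rose by 1.51 ± 0.28, the peroxisomal enzyme gene Ehhadh by 1.11 ± 0.24 and the mitochondrial dehydrogenase gene Acadm by 0.41 ± 0.08, while Ppara was at 0.14 ± 0.16 (adjusted p = 0.62). Oxidative phosphorylation genes rose in 10 of 22 cases (16 adjusted over the list alone, median 0.21, adjusted p = 9.51e-07, and adjusted p = 0.246 with an estimated correlation), among them Ndufb5 at 0.37 ± 0.08. In fatty acid and triglyceride synthesis 1 of 19 rose and 4 fell (1 and 5 adjusted over the list alone, adjusted p = 0.755). Fasn fell by 0.76, Thrsp, a lipogenic nuclear protein, by 1.21 and Scd1 by 0.64 on the log2 scale. The Scd1 call ended without HFD 1 (−0.52, adjusted p = 0.056) and without a filter on low counts (adjusted p = 0.071). Srebf1 was at −0.48 ± 0.21 (adjusted p = 0.11) and passed with limma-voom (−0.59, adjusted p = 0.02) and with the 2 diets fitted alone (−0.49, adjusted p = 0.032).

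Lipid droplet genes were 1 higher and 6 lower of 18 (1 and 6 adjusted over the list alone) without a call (adjusted p = 0.0824). Vldlr and Fabp4 fell by 1.05 and 1.05 on the log2 scale, and Cd36 and Cidec were at −0.33 ± 0.19 (adjusted p = 0.22) and −0.46 ± 0.28 (adjusted p = 0.27). Of the cholesterol list 1 of 23 rose and 4 fell (1 and 5 adjusted over the list alone), with a median of −0.13 (adjusted p = 0.304). Sqle fell further, from 0.83 ± 0.41 to 0.184 ± 0.17 CPM. Bile acid genes were 4 higher and 2 lower of 19 (4 and 3 adjusted over the list alone, adjusted p = 0.0966). Cyp7b1, of the alternative bile acid pathway, rose by 1.98 ± 0.19 and Slc10a1 by 0.68 ± 0.09. Sugar metabolism genes were 6 higher and 3 lower of 17 (7 and 3 adjusted over the list alone, adjusted p = 0.0966). Those that rose include the gluconeogenic genes Pck1 (1.16 ± 0.15), G6pc and Fbp1, and those that fell the glycolytic genes Pklr and Pfkl. Khk was at −0.14 ± 0.13 (adjusted p = 0.5).

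Of 12 male-predominant liver genes 8 rose (9 adjusted over the list alone), with a median of 0.85 (adjusted p = 2.27e-08, and adjusted p = 0.043 with an estimated correlation). Hsd3b5 rose from 5.15 ± 5.44 to 51.6 ± 49.4 CPM, and Cyp2d9, a cytochrome P450, and Serpina1e, a protease inhibitor, rose by 0.84 ± 0.10 and 2.38 ± 0.42. Mup21, of the urinary protein family, rose by 2.22 ± 0.19. Female-predominant genes were 1 lower of 5 (adjusted p = 0.91). Clock genes rose in 5 of 16 cases (6 adjusted over the list alone), with a median of 0.41 (adjusted p = 0.0059, and adjusted p = 0.154 with an estimated correlation). Hlf, an output transcription factor of the clock, rose by 0.38 ± 0.10 and the clock repressor gene Ciart by 2.01 ± 0.56, the latter not passing with limma-voom (adjusted p = 0.078). Zbtb16, a zinc finger transcription factor, rose by 2.10 ± 0.45. Xenobiotic genes were 4 higher and 8 lower of 18 (5 and 9 adjusted over the list alone, adjusted p = 0.288), with Gstm3 at −2.01 ± 0.38. Lists without a call were endoplasmic reticulum stress (1 higher and 2 lower of 15, median 0.04, mean −0.14, adjusted p = 0.91) and adipocyte identity (2 higher and 2 lower of 10, median 0.01, mean −0.42, adjusted p = 0.748). Nat8, an acetyltransferase gene, and Pls1, an actin-bundling protein gene, fell by 2.86 and 2.94 on the log2 scale.

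Compared with the normal diet, the liver of ALL mice had lower cholesterol synthesis transcripts and higher macrophage markers, the latter not called with an estimated correlation. In ALL vs ND 1726 genes were called in liver, 869 higher and 857 lower in ALL, and 2904 with limma-voom. Cholesterol genes were lower in 22 of 23 cases (23 adjusted over the list alone), with a median of −1.39 (adjusted p = 5.53e-33, and adjusted p = 0.0121 with an estimated correlation), Sqle and Idi1 being at −6.26 ± 0.47 and −4.72 ± 0.43. Macrophage markers were 13 higher and 1 lower of 21 (15 and 2 adjusted over the list alone, median 0.87, adjusted p = 7.64e-10, and adjusted p = 0.223 with an estimated correlation). Gpnmb was at 3.64 ± 0.54, Cidea at 3.15 ± 0.57, the zinc finger gene Zfp979 at 3.26 ± 0.45 and Chrna4, an acetylcholine receptor subunit gene, at −6.48 ± 0.58. Inflammatory genes were higher in 9 of 22 cases (13 adjusted over the list alone, median 0.74, adjusted p = 6.43e-07, and adjusted p = 0.276 with an estimated correlation).

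Further lists were called in liver ALL vs ND. Without ND 7, HFD 1 and ALL 8, 9 of 13 calls were made, and female-predominant genes, endoplasmic reticulum stress, neutrophil and mast cell markers and endothelial markers were not called (adjusted p = 0.0583 to 0.0744). Interferon response genes were 1 higher and 6 lower of 15 (1 and 7 adjusted over the list alone, median −0.54, adjusted p = 0.00307, and adjusted p = 0.368 with an estimated correlation). Fatty acid synthesis genes were lower in 6 of 19 cases (adjusted p = 0.00684, and adjusted p = 0.354 with an estimated correlation), and immediate early genes higher in 3 of 14 (6 adjusted over the list alone, adjusted p = 0.000365, and adjusted p = 0.278 with an estimated correlation). The matrix list was called with 0 of 20 members called, at a median of 0.32 (adjusted p = 0.0125, and adjusted p = 0.523 with an estimated correlation). Xenobiotic metabolism (5 higher and 1 lower of 18, adjusted p = 0.0306, and adjusted p = 0.473 with an estimated correlation), male-predominant genes (5 of 12 higher, adjusted p = 0.0275, and adjusted p = 0.354 with an estimated correlation), neutrophil and mast cell markers (1 of 3 higher, adjusted p = 0.0475, and adjusted p = 0.278 with an estimated correlation) and endothelial markers (1 of 13 higher, adjusted p = 0.0414, and adjusted p = 0.56 with an estimated correlation) lost their calls without single libraries (adjusted p of up to 0.119).

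The calls of female-predominant genes (2 of 5 lower, adjusted p = 0.049, and adjusted p = 0.278 with an estimated correlation) and of endoplasmic reticulum stress (5 higher and 1 lower of 15, adjusted p = 0.049, and adjusted p = 0.471 with an estimated correlation) in liver ALL vs ND rested on single libraries, without which the adjusted p reached 0.0979 and 0.165. The other lists were not called, with adjusted p-values from 0.07 for lipid droplets (5 higher and 1 lower of 18) to 0.949 for adipocyte identity (2 of 10 higher, median −0.03, mean 0.24). Among them, no member of antigen presentation (13 tested, adjusted p = 0.534), of oxidative phosphorylation (22 tested, adjusted p = 0.103) or of the lymphocyte list (6 tested, adjusted p = 0.377) was called.

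**Figure D2:**
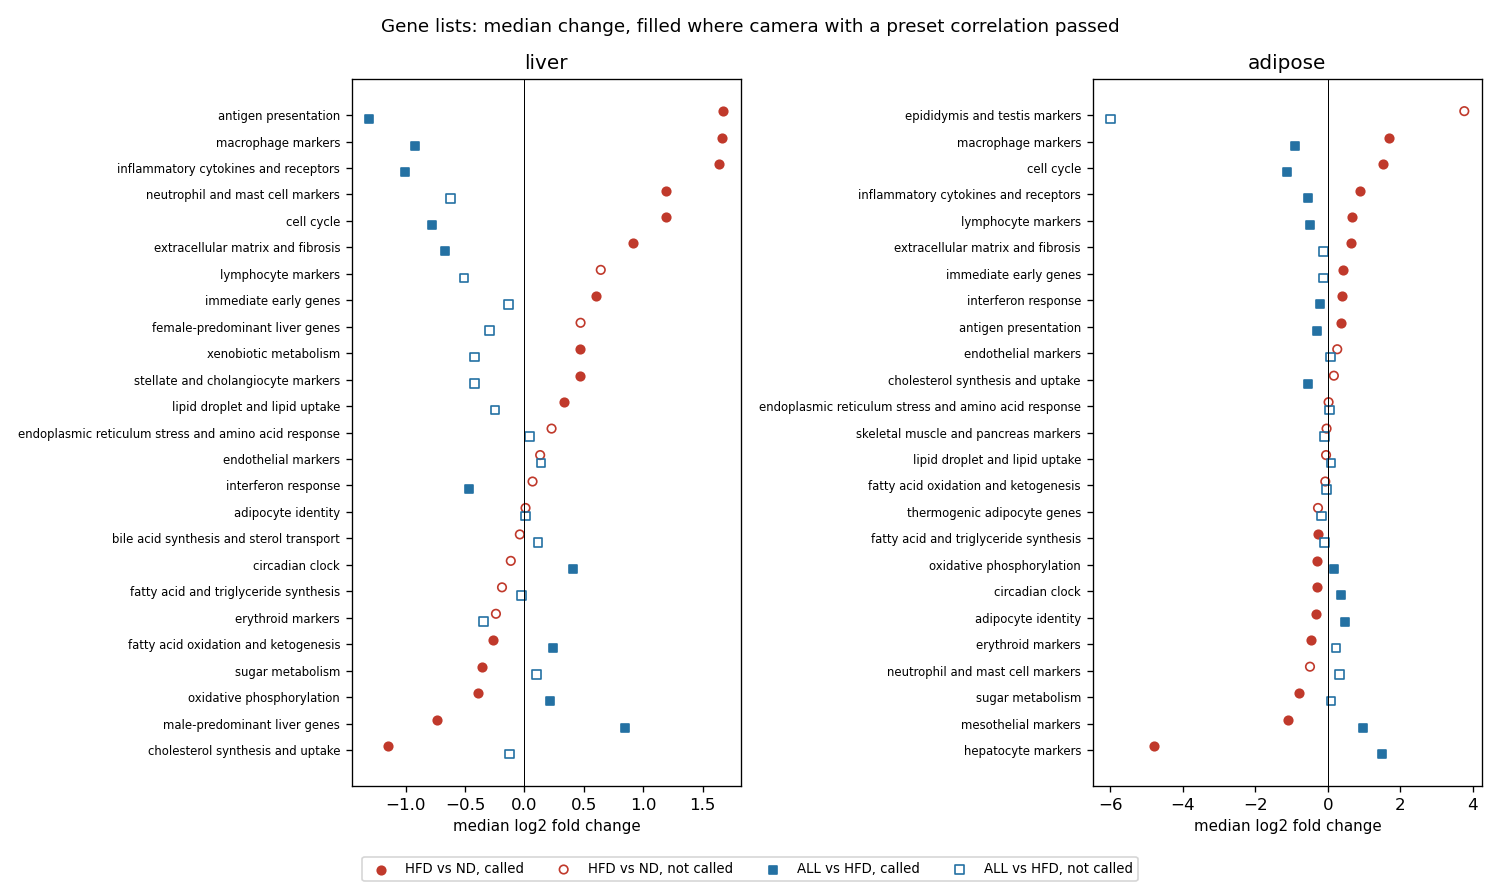
Median log2 fold change over the tested members of each gene list in liver and adipose tissue, with circles for HFD vs ND and squares for ALL vs HFD, filled where camera with the preset correlation called the list. Macrophage markers lie above 0 in HFD vs ND and below 0 in ALL vs HFD in both tissues.

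The adipose libraries differed in transcripts of other cell types. The first principal component held 57.1% of the variance. Duct epithelium genes, a list added after the data had been seen, had mean log2 CPM of 4.79 ± 2.70 in ND, 3.30 ± 2.48 in HFD and 2.64 ± 3.37 in ALL (SD, n = 9), and in an exact permutation test HFD minus ND was −1.49 (p = 0.243), ALL minus HFD −0.65 (p = 0.64) and ALL minus ND −2.15 (p = 0.157). Motile cilia genes were at 5.13 ± 2.89, 3.72 ± 2.70 and 2.93 ± 3.95, with exact permutation p-values of 0.301, 0.623 and 0.193 in the same order. Epididymal head genes reached 9.262 in ND 8, against group means of 0.48 ± 3.39 in ND, −1.50 ± 0.86 in HFD and −1.25 ± 1.21 in ALL. Spermatid genes reached 10.364 in HFD 7 and 5.924 in ND 1, against 1.17 ± 2.06, 1.35 ± 3.54 and 0.07 ± 1.66. Hepatocyte markers were high in ND 1, ND 2 and ND 9, at 5.519, 6.482 and 7.839, and averaged 3.43 ± 2.47 in ND, 1.10 ± 0.59 in HFD and 2.20 ± 0.83 in ALL. In liver the duct epithelium means were 1.30, 1.80 and 1.26, and those of the other added lists of this kind at most −1.83 in each diet.

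**Figure D3:**
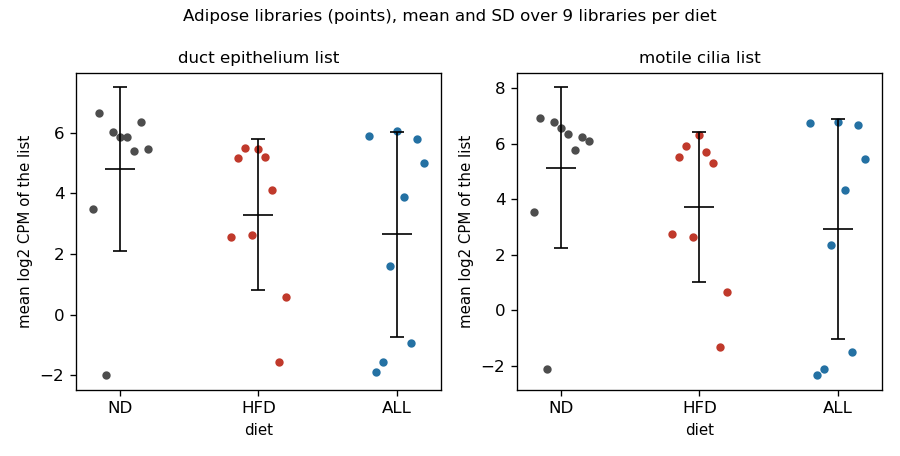
Mean log2 CPM of the duct epithelium and motile cilia lists in each adipose library of ND, HFD and ALL, with points for the 9 libraries of a diet and bars for the mean ± SD. The spread within each diet exceeds the differences between the diet means.

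Adipose tissue of HFD mice held more macrophage, inflammation and cell cycle transcripts than that of ND mice, and fewer of adipocyte identity, fatty acid synthesis and oxidative phosphorylation, though 0 of 25 lists were called with an estimated correlation. Lep, the leptin gene, rose from 983.1 ± 236.8 to 2538 ± 725.1 CPM (log2 fold change 1.37 ± 0.20, adjusted p = 3e-05). Trem2, a receptor of lipid-associated macrophages, rose from 7.13 ± 1.35 to 67.5 ± 41 CPM (3.24 ± 0.44, adjusted p = 1.9e-05), and Adrb3, the adipocyte adrenergic receptor gene, fell from 654 ± 250 to 205 ± 78.7 CPM. Of 16645 genes 3768 were called, 2541 higher and 1227 lower in HFD. DESeq2 gave 2327 higher and 1826 lower, and limma-voom 3978 higher and 4269 lower. Without a filter on low counts the median of all genes was 0.126 in HFD vs ND and −0.123 in ALL vs HFD, against 0.042 and −0.036 with it. Without the 5 libraries that held transcripts of other organs (ND 1, 2, 8 and 9 and HFD 7) 2114 genes were called. Lep (ENSMUSG00000059201) lies on chromosome 6 from 29060220 to 29073877 and Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147.

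Macrophage markers rose in 18 of 21 cases (18 adjusted over the list alone), with a median of 1.68 (adjusted p = 7.03e-16, and adjusted p = 0.203 with an estimated correlation). Itgax, encoding CD11c, rose from 15.8 ± 3.5 to 83.2 ± 41.6 CPM, the pore-forming protein gene Mpeg1 rose by 1.93 ± 0.28 and the integrin gene Itgad by 5.71 ± 0.68. Inflammatory genes rose in 15 of 21 cases (16 adjusted over the list alone), with a median of 0.89 (adjusted p = 8.51e-10, and adjusted p = 0.203 with an estimated correlation). Ccl2 rose by 1.94 ± 0.25, Tnf, the tumour necrosis factor gene, by 1.38 ± 0.31, the inflammasome gene Casp1 by 1.48 ± 0.20 and Il1rn, an interleukin-1 receptor antagonist, by 3.78 ± 0.55. Antigen presentation genes rose in 8 of 13 cases (9 adjusted over the list alone, median 0.37, adjusted p = 5.2e-05, and adjusted p = 0.245 with an estimated correlation), with H2-DMb1 at 0.91 ± 0.16. Interferon response genes rose in 5 of 15 cases, with Ifit2 at 0.69 ± 0.17 and a median of 0.40 (adjusted p = 0.0158, and adjusted p = 0.458 with an estimated correlation), a call that ended without HFD 6 (adjusted p = 0.0681). Lymphocyte markers rose in 5 of 15 cases (9 adjusted over the list alone, median 0.68, adjusted p = 0.00148, and adjusted p = 0.245 with an estimated correlation). The neutrophil and mast cell list went both ways (2 higher and 3 lower of 8, adjusted p = 0.128): S100a8 and Csf3r, of neutrophils, rose and the mast cell protease genes Tpsb2 and Mcpt4 fell.

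Cell cycle genes rose in 15 of 16 cases (16 adjusted over the list alone), with a median of 1.52 (adjusted p = 7.29e-08, and adjusted p = 0.203 with an estimated correlation). HFD 7, the library with spermatid transcripts, had the highest list mean, 5.188 against a group mean of 3.09 ± 0.84 log2 CPM. The mitotic kinase gene Bub1 rose by 3.30 ± 0.69, and by 1.5 without HFD 7 (adjusted p = 0.0016), and Mki67 rose by 1.48 ± 0.28. Extracellular matrix genes were 12 higher and 1 lower of 21 (13 and 1 adjusted over the list alone), with a median of 0.64 (adjusted p = 0.000255, and adjusted p = 0.438 with an estimated correlation). Timp1, a protease inhibitor, rose by 1.64 ± 0.26, Mmp2 by 0.89 ± 0.17 and the collagen gene Col1a1 by 0.64 ± 0.18, which did not pass without the 5 libraries (0.56, adjusted p = 0.12). Immediate early genes rose in 6 of 15 cases (7 adjusted over the list alone, median 0.43, adjusted p = 0.00148, and adjusted p = 0.245 with an estimated correlation). Endothelial markers had 1 of 13 higher (adjusted p = 0.109).

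Adipocyte identity genes were 1 higher and 8 lower of 19 (1 and 10 adjusted over the list alone), with a median of −0.33 (adjusted p = 0.000255, and adjusted p = 0.438 with an estimated correlation). The member that rose was Lep, whereas Adrb3 and Retn, the resistin gene, were at −1.68 ± 0.24 and −1.03 ± 0.18. Adipoq, the adiponectin gene, was at −0.33 ± 0.15 (adjusted p = 0.12) and passed with the duct epithelium mean as a covariate (−0.42, adjusted p = 0.017). Fatty acid synthesis genes fell in 6 of 20 cases (7 adjusted over the list alone), with a median of −0.27 (adjusted p = 0.000399, and adjusted p = 0.245 with an estimated correlation). Fasn fell from 3022 ± 1408 to 1321 ± 316 CPM, and the elongase and carboxylase genes Elovl6 and Acaca fell by 1.23 and 1.25 on the log2 scale. Sugar metabolism genes fell in 5 of 17 cases (1 higher and 5 lower adjusted over the list alone), with a median of −0.80 (adjusted p = 0.00169, and adjusted p = 0.203 with an estimated correlation). They were Pck1 (−1.02 ± 0.21), of glyceroneogenesis in adipocytes, Pygl (−0.76 ± 0.14), and Gckr, G6pc and Slc2a2, which are genes of the liver. Oxidative phosphorylation genes were 1 higher and 16 lower of 22 (1 and 19 adjusted over the list alone, median −0.29, adjusted p = 4.07e-10, and adjusted p = 0.203 with an estimated correlation), with Uqcrc2 at −0.47 ± 0.07 and Atp5c1 at −0.52 ± 0.08.

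Lipid droplet genes were 2 higher and 3 lower of 18 (adjusted p = 0.419). Plin2, a droplet coat protein, rose by 0.87 ± 0.19, the acyltransferase gene Mogat1 fell by 1.29 on the log2 scale, and Cd36 was at 0.34 ± 0.17 (adjusted p = 0.14). The thermogenic list was 2 higher and 1 lower of 10, with a median of −0.27 and a mean of 0.10 (adjusted p = 0.754), and Otop1, a proton channel gene, rose by 3.36 ± 0.45. Clock genes fell in 5 of 16 cases (median −0.30, adjusted p = 0.0112, and adjusted p = 0.203 with an estimated correlation), among them the repressor gene Nr1d1 at −0.51 ± 0.15, which did not pass without the 5 libraries (−0.44, adjusted p = 0.1). No call was made for cholesterol synthesis (5 higher and 2 lower of 22, adjusted p = 0.338), fatty acid oxidation (2 higher and 2 lower of 21, adjusted p = 0.754) or endoplasmic reticulum stress (3 higher and 1 lower of 15, adjusted p = 0.852).

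Markers of other organs moved with the diet as well. Hepatocyte markers fell in 10 of 12 cases (12 adjusted over the list alone), with a median of −4.80 (adjusted p = 7.16e-06, and adjusted p = 0.245 with an estimated correlation), and the list was called without the 5 libraries too. In HFD adipose tissue 5 of the 13 listed markers reached 1 CPM, and 3 reached 10 CPM. Alb, the albumin gene, was at 415 ± 752 CPM in ND and 16.8 ± 9.72 in HFD (−4.63 ± 0.90), and without the 5 libraries at −0.63 (adjusted p = 0.32). Apoa2 and Fabp1, at −6.93 ± 1.34 and −7.98 ± 1.62, gave −1.0 (adjusted p = 0.38) and −1.27 (adjusted p = 0.47) without them, and Apob and Gc, at −7.06 ± 1.67 and −6.77 ± 1.53, gave −0.58 (adjusted p = 0.78) and 0.02. Without HFD 9, Apob and Gc were at −11.52 (adjusted p = 0.00069) and −10.51 (adjusted p = 0.00041). Apoa2 and Apob encode apolipoproteins, Fabp1 a liver fatty acid carrier and Gc a vitamin D carrier. With limma-voom none of the 5 passed (adjusted p = 0.051 to 0.13). Cyp2e1, a cytochrome P450 that is on this list and also made in adipose tissue, fell from 2231 ± 596.7 to 590.4 ± 289.6 CPM.

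Mesothelial markers, of which HFD adipose tissue expressed 11 of 12 at 1 CPM or more, fell in 4 of 12 cases (6 adjusted over the list alone), with a median of −1.11 (adjusted p = 0.000343, and adjusted p = 0.203 with an estimated correlation). Upk3b and Lrrn4 were at −1.43 ± 0.40 and −1.38 ± 0.37. The list means were 3.84 ± 0.78 log2 CPM in ND, 2.70 ± 0.76 in HFD and 3.73 ± 0.19 in ALL. Epididymis and testis markers were not called (0 of 4, median 3.76, mean 2.02, adjusted p = 0.567), nor were muscle and pancreas markers (1 of 3 higher, median −0.04, mean 0.07, adjusted p = 0.567). Adam7, an epididymal gene, was at −3.64 ± 1.34 (adjusted p = 0.051), and at −1.25 without ND 8 (adjusted p = 0.46). The erythroid list was called with 0 of 6 members (median −0.48, adjusted p = 0.0361, and adjusted p = 0.458 with an estimated correlation), and this ended without ND 1, 3 or 9 or HFD 1, 2, 3 or 7, at an adjusted p of up to 0.183, and without the 5 libraries, at 0.351. Among the largest rises, Lhx8, a homeobox gene, had 538 counts over the HFD libraries and 2 over the ND libraries, a ratio of 257 in CPM (95% counting interval 70.8 to 2130), and Gpr50, an orphan receptor gene, rose by 5.80 ± 0.61. Dnah8, a dynein gene of sperm tails, was at 5.35 ± 1.43 (adjusted p = 0.009), and at −1.07 without HFD 7 (adjusted p = 0.17).

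**Figure D4:**
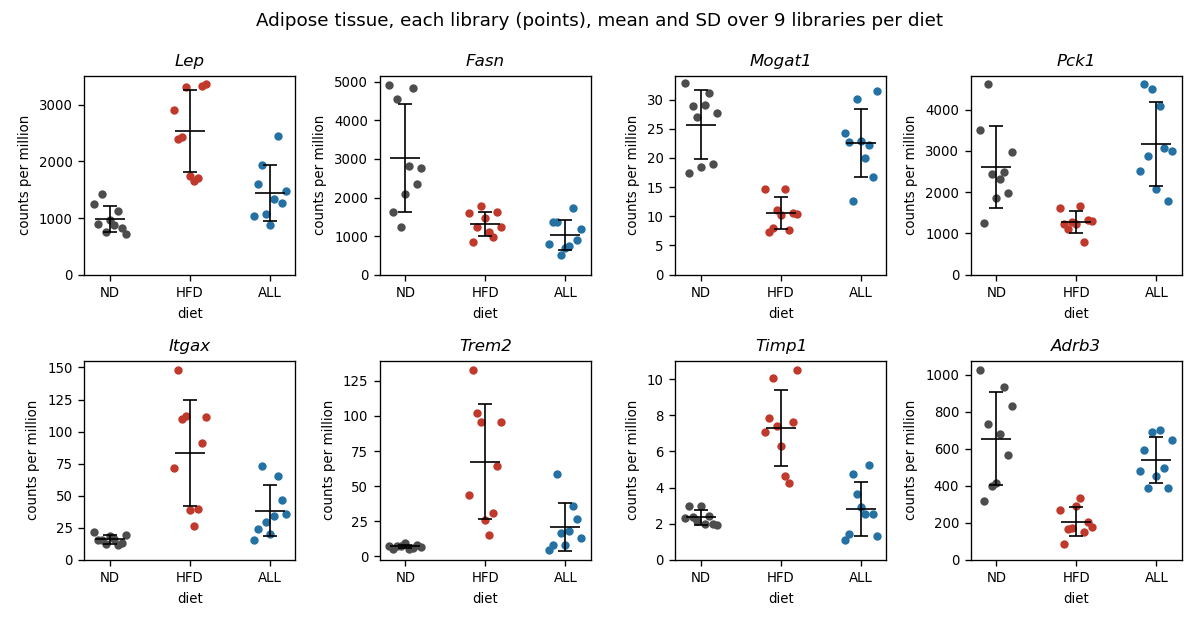
CPM per adipose library (linear axes, 0 included) for 8 genes in ND, HFD and ALL, with points for the 9 libraries of each diet and bars for the mean ± SD. Lep, Itgax, Trem2 and Timp1 lie higher in HFD than in ND, and Adrb3, Mogat1 and Pck1 lie lower.

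With D-allulose on the high-fat diet, adipose tissue held fewer macrophage, cholesterol synthesis and cell cycle transcripts than with the high-fat diet alone, and more of adipocyte identity, again with 0 lists called under an estimated correlation. Lep fell from 2538 ± 725.1 to 1450 ± 494.2 CPM (log2 fold change −0.81 ± 0.19, adjusted p = 0.007), and Adrb3 rose from 205 ± 78.7 to 537 ± 124 CPM (1.39 ± 0.24, adjusted p = 0.00048). Pck1 rose from 1283 ± 260.9 to 3175 ± 1020 CPM (1.31 ± 0.21, adjusted p = 0.00028). In ALL vs HFD 2842 genes were called, 1130 higher and 1712 lower in ALL, and with DESeq2 1446 higher and 1489 lower. The count was 4327 without a filter on low counts (1043 higher and 3284 lower), 1848 with the 2 diets fitted alone, 1892 with the replicate number as a block and 4657 without the 5 libraries and with the duct epithelium mean as a covariate.

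Macrophage markers fell in 13 of 21 cases (17 adjusted over the list alone), with a median of −0.91 (adjusted p = 1.01e-08, and adjusted p = 0.362 with an estimated correlation). Trem2, Itgax and Lgals3 were at −1.67 ± 0.41, −1.13 ± 0.31 and −1.18 ± 0.28. Inflammatory genes fell in 7 of 21 cases (11 adjusted over the list alone, median −0.54, adjusted p = 2.75e-06, and adjusted p = 0.31 with an estimated correlation). Ccl2 and Casp1 fell by 1.55 and 0.94 on the log2 scale, and Tnf was at −0.78 ± 0.30 (adjusted p = 0.075), passing without the 5 libraries (−0.89, adjusted p = 0.046). Antigen presentation genes fell in 5 of 13 cases (median −0.31, adjusted p = 0.000843, and adjusted p = 0.51 with an estimated correlation), with H2-DMb1 at −0.93 ± 0.16 and the class I gene H2-K1 at −0.58 ± 0.11. Interferon response genes fell in 3 of 15 cases (median −0.23, adjusted p = 0.00523, and adjusted p = 0.51 with an estimated correlation). Lymphocyte markers fell in 3 of 15 cases (median −0.49, adjusted p = 0.0152, and adjusted p = 0.51 with an estimated correlation), a call that ended without HFD 6 or HFD 8, at an adjusted p of up to 0.0649. In the neutrophil and mast cell list 2 rose and 1 fell of 8 (adjusted p = 0.419), and the latter, S100a8, was at −1.83 ± 0.30.

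Cell cycle genes fell in 14 of 16 cases (16 adjusted over the list alone), with a median of −1.13 (adjusted p = 2.15e-07, and adjusted p = 0.312 with an estimated correlation). The replication helicase gene Mcm5 was at −0.86 ± 0.18. Bub1 and the cyclin gene Ccnb2, at −2.75 ± 0.67 and −2.66 ± 0.62, gave −0.94 (adjusted p = 0.043) and −0.94 (adjusted p = 0.018) without HFD 7, and did not pass with the replicate number as a block (adjusted p = 0.087 and 0.052). Cholesterol genes fell in 13 of 22 cases (16 adjusted over the list alone), with a median of −0.55 (adjusted p = 4.78e-09, and adjusted p = 0.0715 with an estimated correlation). The sterol reductase gene Dhcr7 was at −1.13 ± 0.18. Fatty acid synthesis genes were 1 higher and 1 lower of 20 (adjusted p = 0.602), with the desaturase gene Scd2 at −1.23 ± 0.20 and Fasn at −0.35 ± 0.25 (adjusted p = 0.35).

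Adipocyte identity genes were 9 higher and 1 lower of 19 (13 and 2 adjusted over the list alone), with a median of 0.47 (adjusted p = 4.04e-07, and adjusted p = 0.377 with an estimated correlation). The member that fell was Lep. Retn and Adig, an adipogenesis gene, rose by 0.92 ± 0.17 and 0.70 ± 0.13. Adipoq was at 0.47 ± 0.15 (adjusted p = 0.038), a call that ended without any 1 of 12 libraries (adjusted p of up to 0.084), without a filter on low counts (adjusted p = 0.052) and with the replicate number as a block (adjusted p = 0.064). Lipid droplet genes were 6 higher and 1 lower of 18 (6 and 2 adjusted over the list alone, adjusted p = 0.0994), a list that passed with the 2 diets fitted alone (adjusted p = 0.0143). Mogat1 rose by 1.10 ± 0.17 and the coat protein gene Plin4 by 0.83 ± 0.18, and Cd36 was at 0.01 ± 0.17 (adjusted p = 0.99). Sugar metabolism genes were 3 higher and 3 lower of 17, with a median of 0.09 and a mean of −0.32 (adjusted p = 0.602). Oxidative phosphorylation genes were 5 higher and 1 lower of 22 (6 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.000994, and adjusted p = 0.51 with an estimated correlation), with Sdha at 0.25 ± 0.08, a call that ended without ALL 2, 4 or 9 (adjusted p of up to 0.057).

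Clock genes rose in 4 of 16 cases in adipose ALL vs HFD (median 0.35, adjusted p = 0.0013, and adjusted p = 0.189 with an estimated correlation), among them Nr1d1 at 0.88 ± 0.15 and Per2 at 0.87 ± 0.16. The matrix list was not called (2 of 21 lower, adjusted p = 0.206), with Timp1 at −1.37 ± 0.25 and Col1a1 at −0.38 ± 0.18 (adjusted p = 0.15), and passed without the 5 libraries (adjusted p = 0.0338) and with the covariate (adjusted p = 0.0193). Immediate early genes were 1 higher and 5 lower of 15 (adjusted p = 0.164), and passed without the 5 libraries (adjusted p = 0.0134). Thermogenic genes were 1 higher and 2 lower of 10 (adjusted p = 0.181), with Otop1 at −2.86 ± 0.43. No call was made for fatty acid oxidation (2 of 21 higher, median −0.03, mean 0.05, adjusted p = 0.602), endoplasmic reticulum stress (3 higher and 2 lower of 15, median 0.05, mean −0.04, adjusted p = 0.519), erythroid cells (0 of 6, adjusted p = 0.164) or endothelial cells (2 of 13 higher, adjusted p = 0.164).

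Mesothelial markers rose in 6 of 12 cases in adipose ALL vs HFD, with a median of 0.96 (adjusted p = 2.94e-05, and adjusted p = 0.194 with an estimated correlation), and Upk3b and Lrrn4 were at 1.98 ± 0.41 and 1.98 ± 0.38. The hepatocyte list was called with 1 of 12 members higher, Cyp2e1 at 1.88 ± 0.28, and a median of 1.48 (adjusted p = 0.00553, and adjusted p = 0.51 with an estimated correlation). Epididymis and testis markers were lower in 3 of 4 cases (median −6.0, adjusted p = 0.602), and muscle and pancreas markers 1 higher and 1 lower of 3 (adjusted p = 0.419). Prm2, a sperm protamine gene, and Crisp2, a sperm protein gene, at −5.92 ± 1.69 and −6.25 ± 1.49, gave 0.33 (adjusted p = 0.87) and −1.05 (adjusted p = 0.37) without HFD 7. Lhx8 was at −6.19 ± 0.57. Large rises were those of Acsm3, an acyl-CoA synthetase, Mycl, a MYC family member, and Fam13a, at 2.82 ± 0.38, 2.49 ± 0.36 and 2.48 ± 0.34.

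Adipose tissue of ALL mice differed from that of ND mice at 417 genes, of which 279 were higher and 138 lower in ALL. Macrophage markers were higher in 7 of 21 cases (15 adjusted over the list alone, median 0.75, adjusted p = 2.29e-08, and adjusted p = 0.378 with an estimated correlation). Fatty acid synthesis genes were lower in 6 of 20 cases (1 higher and 11 lower adjusted over the list alone, median −0.41, adjusted p = 8.5e-08, and adjusted p = 0.141 with an estimated correlation). Cholesterol genes were lower in 5 of 22 (12 adjusted over the list alone, median −0.40, adjusted p = 1.05e-09, and adjusted p = 0.0534 with an estimated correlation). The G-protein regulator gene Rgs1 was at 2.77 ± 0.48, the tetraspanin-like gene Tm4sf19 at 2.77 ± 0.60 and Itgad at 2.65 ± 0.62. The count of adipose ALL vs ND genes depended on single libraries: it ranged from 146 without ALL 2 and 147 without ALL 6 to 912 without ND 3 and 961 without HFD 7. There were 18 called genes without the 5 libraries, 184 with the duct epithelium mean as a covariate, 991 with DESeq2, 4707 with limma-voom (more than its 3509 for ALL vs HFD) and 189 without a filter on low counts. With the replicate number as a block it was 62, and of Rgs1, Tm4sf19, Itgad, C4bp, Defb42 and Ido1 none was called (adjusted p = 0.056 to 0.58).

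The other lists of adipose ALL vs ND with a call were sugar metabolism (2 of 17 lower, 5 adjusted over the list alone, adjusted p = 0.000219, and adjusted p = 0.141 with an estimated correlation), inflammation (2 of 21 higher, 6 adjusted over the list alone, adjusted p = 0.000589, and adjusted p = 0.378 with an estimated correlation) and oxidative phosphorylation (2 of 22 lower, 8 adjusted over the list alone, adjusted p = 1.28e-07, and adjusted p = 0.378 with an estimated correlation). The matrix list (1 of 21 higher, adjusted p = 0.000382, and adjusted p = 0.582 with an estimated correlation) was not called without the 5 libraries (adjusted p = 0.0801) or with the covariate (adjusted p = 0.197). Immediate early genes (3 of 15 higher, adjusted p = 0.00485, and adjusted p = 0.378 with an estimated correlation) and endothelial markers (0 of 13, 3 higher adjusted over the list alone, median 0.36, adjusted p = 3.76e-05, and adjusted p = 0.378 with an estimated correlation) were called too. Hepatocyte markers were lower in 6 of 12 (median −3.87, adjusted p = 0.00189, and adjusted p = 0.533 with an estimated correlation), and without the 5 libraries the direction turned, without a call (adjusted p = 0.383).

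C4bp, a complement regulator gene, Defb42, an epididymal defensin gene, and Ido1, a tryptophan dioxygenase gene, were at −5.91 ± 1.31, −5.34 ± 1.37 and −5.01 ± 1.25 in adipose ALL vs ND. Without ND 8 they were at −2.38, −1.21 and −0.36 (adjusted p = 0.15 to 0.83). The calls of Defb42 and Ido1 ended also without ALL 2, 3, 4, 6 or 7, and those of Defb42 and Itgad without ND 2, and of Itgad without ALL 3 or 7. Itgad, Rgs1 and Tm4sf19 were, without the 5 libraries, at 2.58, 2.91 and 2.78 (adjusted p = 0.11 to 0.23). The other lists were not called, with adjusted p-values from 0.062 for thermogenic genes (1 of 10 lower) to 0.956 for fatty acid oxidation (1 higher and 1 lower of 21). No member was called of antigen presentation (13 tested, adjusted p = 0.199), interferon response (15, adjusted p = 0.857), adipocyte identity (19, adjusted p = 0.262), the cell cycle (16, adjusted p = 0.238), the clock (16, adjusted p = 0.687) or mesothelium (12, adjusted p = 0.782). Lipid droplet genes were 2 lower of 18, with a median of 0.17 and a mean of −0.06 (adjusted p = 0.343). Endoplasmic reticulum stress passed without the 5 libraries (adjusted p = 0.0113), erythroid cells with the covariate (adjusted p = 0.0277), and thermogenic genes with the covariate (adjusted p = 0.0432) and with the 2 diets fitted alone (adjusted p = 0.0203).

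Many genes changed by the high-fat diet moved the other way with D-allulose. In liver 1657 genes were called in both HFD vs ND and ALL vs HFD in opposite directions, 1106 of them higher in HFD vs ND and 551 lower, while 39 were called in the same direction. In ALL vs ND 1431 of the 1657 were not called, 189 were still on the HFD side of ND and 37 had passed beyond ND. In adipose tissue 1798 genes were called in opposite directions, 1290 higher in HFD vs ND and 508 lower, and 2 in the same direction. The adipose count was 1089 with the 2 diets fitted alone and 1174 with the replicate number as a block. Without the 5 libraries it was 1250, of which 998 are among the 1798. Of the 1798, 1759 were not called in ALL vs ND, 35 were on the HFD side and 4 beyond ND, which rests on an ALL vs ND count of 417 that was 18 to 4707 with other settings. Both comparisons use the same HFD libraries, which alone gives opposite changes, and HFD 7, with spermatid transcripts, is in both. In 20 simulated sets without an effect 0 genes were called in opposite directions, which decides nothing, as sets without an effect give few calls. Independent lists of these sizes would share 406.3 genes in liver and 344.7 in adipose tissue. With different HFD libraries in each comparison, 5 against ND and 4 against ALL, 577 genes were called in opposite directions in liver, where independent lists would share 111.5, and 150 in adipose tissue, where they would share 17.7. The covariance of the log2 fold changes over genes was −0.152 in liver, against −0.017 simulated and −0.132 with the split, and −0.444 in adipose tissue, against −0.056 simulated and −0.181 with the split.

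The effect of HFD vs ND differed between adipose tissue and liver at 2214 of 17414 genes, 694 with a more positive and 1520 with a more negative change in adipose tissue, and at 1392 without the 5 libraries. For ALL vs HFD the effect differed at 1629 genes, 887 more positive and 742 more negative. Among named genes tested in both tissues, 53 of 89 differed in HFD vs ND, 12 more positive and 41 more negative in adipose tissue, and 27 of 82 in ALL vs HFD, 19 and 8. Some were named for a large difference, and several of the 41 are hepatocyte genes, whose markers were high in adipose ND 1, 2 and 9. Sterol genes such as Sqle, Idi1 and Cyp51 changed more positively in adipose tissue in HFD vs ND, by 3.97, 3.53 and 2.34 on the log2 scale. In ALL vs HFD the matrix genes Col3a1 and Col1a1 differed by 1.24 and 1.29, the change being the more negative in liver.

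The largest differences between tissues in HFD vs ND were those of Nanp at 6.23 ± 1.31 (adipose 2.92, liver −3.32), Chrna4 at 5.70 ± 0.78 and Slc6a21 at 5.19 ± 1.53, and, negative, those of Akr1c6, Hsd17b6 and Cyp3a11 at −8.81 ± 1.49, −8.39 ± 1.41 and −8.25 ± 1.44. The last of these are liver enzymes of steroid and drug metabolism. Akr1c6 had 1 count in HFD and 1060 in ND adipose tissue, a ratio of 0.000902 (95% counting interval 2.28e-05 to 0.00504). Hsd17b6 had 0 and 220 counts, for which the 95% counting interval of the ratio reaches 0.0162. Without the 5 libraries Akr1c6, Hsd17b6 and Cyp3a11 were at −2.66, −2.26 and −1.06 (adjusted p = 0.26 to 0.68), and Slc6a21 was at −0.33, and at −0.01 with DESeq2. In ALL vs HFD the largest were those of Hhex, a homeobox gene, at 5.09 ± 1.10 (adipose 2.26, liver −2.83), Trim29 at 4.87 ± 0.84, Mup20 at 4.84 ± 1.38, Slc6a21 at −6.88 ± 1.65, St8sia3 at −6.78 ± 1.51 and Trim80 at −6.76 ± 1.57. Trim29 had 0 counts in liver ALL and 17 in liver HFD (95% counting interval of the ratio up to 0.244). With diet and replicate number as a block in limma-voom, Hhex was at 1.46 (adjusted p = 0.5), Mup20 at 3.81 (adjusted p = 0.088) and Trim29 at 1.92 (adjusted p = 0.011), and Slc6a21, St8sia3 and Trim80 were not called (adjusted p = 0.34 to 0.67). Without the 5 libraries Slc6a21, St8sia3 and Trim80 were at −0.37, −0.50 and −0.66 (adjusted p = 0.68 to 0.86), and with DESeq2 at −0.58, −2.74 and −1.28 (adjusted p = 0.1 to 0.74).

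Genes with near-identical copies share reads, so the values of Gsta1, Gstm3, Serpina1e, Mup20, Mup21, Cyp2d9, Cyp4a14, Orm3, Tgtp1 and the H2 genes are uncertain as to which copy they measure.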

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

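The fits without 5 adipose libraries and with the duct epithelium covariate were added after the data had been seen, and the tests on random removals and on the share of hepatocytes were chosen only after the result was seen; the other tests were planned. Single libraries were compared with the other 8 of their diet by gap over range, for the genes named and the list means. Of 951 such groups 82 had a library apart, where chance gives about 1 in 20. Those for list means and for genes with values of that tissue in the report, 41, follow.

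In liver the libraries apart were ALL 5 for Srebf1 (41.9 CPM), ND 6 and HFD 2 for Cd36 (88.2 and 241), ND 2 for Icam1 (13.2), ND 4 for Top2a (0.247), HFD 6 for Gpnmb (4.15) and Ehhadh (2060), HFD 7 for Orm3 (8.61) and HFD 2 for Zbtb16 (30.2). ALL 9 stood apart for Cidec (25.8 CPM), Mmp13 (0) and St8sia3 (0.447), ND 7 and HFD 1 for Akr1c6 (2910 and 2090) and HFD 5 for Hsd17b6 (71.6). Of list means in log2 CPM, ND 4 was apart for interferon response (4.082) and the cell cycle (0.034), and ALL 4 for female-predominant genes (0.459). In adipose tissue HFD 7 was apart in 21 of all groups screened, among them Sdha (310 CPM), Bub1 (49.7), Dnah8 (1200), Ccnb2 (90.2), Prm2 (3370), Crisp2 (1240) and Trim29 (2.83), and the list means of antigen presentation (7.109), the cell cycle (5.188) and epididymis and testis (9.068). HFD 9 was apart for Fabp1 (1.03), Apob (3.56), Gc (3.17) and hepatocyte markers (2.47), and ND 8 for Defb42 (262) and Ido1 (272). The rest were ND 4 for Otop1 (0), ND 2 for Lrrn4 (2.11), ND 1 for Prm2 (198), ALL 5 for Ido1 (3.59), ND 9 for fatty acid oxidation (6.928), and ND 3 for sugar metabolism (2.905) and mesothelial markers (2.085).

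Diet effects that differed between tissues in the interaction test are given as adipose minus liver log2 fold change. For HFD vs ND sterol genes were Sqle 3.97, Idi1 3.53, Cyp51 2.34 and Tm7sf2 1.76. Lipid synthesis genes were Srebf1 −1.13, Fasn −1.50, Acacb 0.99, Elovl6 −1.05 and Acaca −1.70. Lipid storage and uptake genes were Cidec −1.78, Cidea −5.51, Fabp4 −2.36, Lpl −2.67, Vldlr −1.29, Plin2 0.85, Mogat1 −2.41, Adipoq −2.74 and Adrb3 −1.33. Oxidation, bile acid and sugar genes were Cyp4a14 −6.04, Ppara −0.78, Uqcrc2 −0.37, Cyp7a1 −4.34, Abcg5 −4.22, Slc10a1 −5.31 and Pygl −0.87. Immune genes were Icam1 −1.52, Tlr2 −1.01, Il1rn 3.10, Lyz2 −0.90, Cd74 −1.72, H2-Aa −1.62 and H2-DMb1 −1.13, and matrix genes Col3a1 −1.15, Col1a1 −1.54 and Timp1 −1.41. Detoxification and liver genes were Gsta1 −4.94, Gstm3 −3.46, Cyp17a1 3.82, Cyp2e1 −2.02, Alb −4.07, Apoa2 −6.59, Fabp1 −7.34, Apob −7.26, Gc −6.88, Akr1c6 −8.81, Hsd17b6 −8.39 and Cyp3a11 −8.25. Others were Sdcbp2 −4.95, Orm3 −5.00, Chrna4 5.70, Dnah8 5.08, Nanp 6.23 and Slc6a21 5.19. Those of hepatocyte genes, such as Cyp7a1, Slc10a1 and Alb, may come from liver transcripts in adipose ND libraries.

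For ALL vs HFD, with 1629 genes called in all, lipid and sterol genes were Cyp7b1 −2.42, Dhcr7 −1.11, Cidec 1.10, Vldlr 0.64, Fabp4 1.30, Plin4 2.06, Mogat1 1.51, Ehhadh −1.69, Acadm −0.51, Acsm3 2.69 and Adig 2.23. Immune and matrix genes were Icam1 0.85, H2-Aa 1.23, S100a8 −1.40, Col3a1 1.24 and Col1a1 1.29. Others were Slc39a4 3.90, Nat8 3.05, Cyp2e1 1.81, Mycl 2.43, Fam13a 1.60, Hhex 5.09, Trim29 4.87, Mup20 4.84, Slc6a21 −6.88, St8sia3 −6.78 and Trim80 −6.76.

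Calls in adipose tissue were weighed against transcripts of other organs. With the duct epithelium mean as a covariate 89.9% of the HFD vs ND calls and 99.2% of the ALL vs HFD calls were still made in the same direction, above the 66% set beforehand, which argues against unequal shares of that epithelium as the cause. Without the 5 libraries 72.4% of the ALL vs HFD calls were still made, which argues against transcripts of other organs as their cause, but 48.4% of the HFD vs ND calls, under the 50% set beforehand. The condition that no random removal gives as few was added after that value was seen. Over the same 40 random removals the share of HFD vs ND calls kept was 28.8% to 68.7%, and 25 gave as few. Fewer libraries or transcripts of other organs could thus account for the loss. The diet stays open as well, as a biological explanation: lost calls of liver, testis and epididymis genes decide nothing, as the libraries were chosen by these.

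Macrophage markers in liver, 1.95 ± 0.15 (SE) higher in HFD than ND on the log2 scale, might reflect a lower share of hepatocyte RNA. Endothelial markers were 0.19 ± 0.17 higher (exact permutation p = 0.271), and the gap between both lists was 1.76 ± 0.15 (exact permutation p = 4.11e-05, the smallest the permutations can give), which argues against that share as the whole cause. A change in the macrophages themselves, in number or in transcripts per cell, stays open as a hypothesis, and neither was tested.

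Other splits of the same libraries gave as many called genes in 1 of 100 cases, the real split included, for liver HFD vs ND (3847, highest other 2178), liver ALL vs HFD (2799 and 746), adipose HFD vs ND (3768 and 1875), adipose ALL vs HFD (2842 and 1474) and adipose ALL vs ND (417 and 37), and in 2 for liver ALL vs ND (1726 and 1906). Chance is unlikely for these and for the tissue differences, at 1 of 60 splits (2214 and 322, 1629 and 47). For opposite calls in liver (1657 and 0) and adipose tissue (1798 and 102) the splits decide nothing, as most give few calls. For the number of lists called chance is not excluded, with lower but unadjusted rates in liver HFD vs ND (15 called, highest other 18, 4 of 100 splits), liver ALL vs ND (13 and 13, 3) and adipose HFD vs ND (16 and 18, 3). The others were liver ALL vs HFD (10 and 14, 20), adipose ALL vs HFD (12 and 15, 8) and adipose ALL vs ND (10 and 16, 33). The other splits gave a median of 8, 6 and 7 lists in liver (HFD vs ND, ALL vs HFD, ALL vs ND) and 9, 8 and 8 in adipose tissue, so many lists pass with diets mixed.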

How the results depend on the processing

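The fits without libraries chosen for their content and with the covariate were added after the data had been seen; the other settings were planned. Verdicts without single libraries or with a fold change minimum are not counted here. On named genes 1573 verdicts kept direction and threshold side, 83 lost the call, 13 gained one, 10 moved and 11 reversed. For gene lists these counts were 719, 80, 13, 12 and 1, and most of the lost list calls came from the estimated correlation, with which 3, 1 and 1 lists were called in liver (HFD vs ND, ALL vs HFD, ALL vs ND) and 0, 0 and 0 in adipose tissue by camera, against 15, 10, 13, 16, 12 and 10 with the preset one. Causes were not tested where none is given.

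With a log2 fold change of at least 1 asked for, fewer genes can pass: 922, 540 and 333 in liver and 1110, 855 and 128 in adipose tissue. In liver ALL vs ND limma-voom called 2904 genes. In adipose HFD vs ND it called 8247, and 2114 were called without the 5 libraries, where random removals of as many libraries gave like losses. In adipose ALL vs HFD the counts were 4327 without a filter, 1848 with the 2 diets alone and 4657 without the 5 libraries and with the covariate. In adipose ALL vs ND they were 991 with DESeq2, 4707 with limma-voom, 189 without a filter, 18 without the 5 libraries, 184 with the covariate and 89 with both. Opposite adipose calls were 1089 with the 2 diets alone, and the HFD vs ND tissue difference 1392 without the 5 libraries.

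Values that turned in direction were these. Dnah8 in adipose HFD vs ND was −0.37 with DESeq2, −0.22 with limma-voom, −0.44 without the 5 libraries and −0.33 with the covariate as well, since its rise rests on HFD 7. Gc in the same comparison was 0.02 without the 5 libraries. Prm2 in adipose ALL vs HFD was 0.02 with limma-voom, 0.34 without the 5 libraries and 0.42 with the covariate as well. Ido1 in adipose ALL vs ND was 0.27 without the 5 libraries and with the covariate. Slc6a21 in the tissue difference HFD vs ND was −0.01 with DESeq2 and −0.33 without the 5 libraries, and the hepatocyte list in adipose ALL vs ND turned without them (adjusted p = 0.383).

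With each library left out in turn the called genes ranged from 3241 to 4401, 2361 to 2982 and 1338 to 2044 in liver, and from 3092 to 4211, 2227 to 3066 and 146 to 961 in adipose tissue. The lists called ranged over 15 to 18, 10 to 12, 9 to 13, 15 to 16, 11 to 14 and 10 to 12. With the replicate number as a block 3550, 2480 and 1465 genes were called in liver, 2812, 1892 and 62 in adipose tissue, and 1174 were opposite in adipose tissue. The numbers do not pair libraries: deviations of libraries with the same number correlated above 0.1 in 3 of 27 pairs in liver, 11 of 27 in adipose tissue and 4 of 27 across tissues. In simulated data 75 to 77% of 2-fold changes were found in adipose tissue, so genes not called may still differ.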

Other observations

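The tests on clock and glucocorticoid genes were chosen only after the result was seen. Of the genes that respond to glucocorticoids, Fkbp5, a chaperone of their receptor, chosen after its values were seen, rose in ALL vs HFD by 1.46 in liver (adjusted p = 3.2e-05) and 0.95 in adipose tissue (adjusted p = 0.00067), and Zbtb16 by 2.10 (adjusted p = 0.0015) and 1.08 (adjusted p = 6.3e-05). The mean of the added glucocorticoid response list was 4.72 ± 0.32, 4.95 ± 0.25 and 5.26 ± 0.43 log2 CPM in ND, HFD and ALL liver (SD, n = 9) and 5.79 ± 0.25, 5.71 ± 0.22 and 6.25 ± 0.43 in adipose tissue. Klf9 and Ddit4, other responders, rose in adipose tissue by 0.68 and 0.92, and of the clock genes Tef rose in both, by 0.52 and 0.35.

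Another time of day at collection could raise such genes. The clock phase score (period and output genes minus Arntl, Clock and Npas2) was higher in ALL than HFD by 0.32 ± 0.20 in adipose tissue (SE, exact permutation p = 0.12) and by 0.80 ± 0.46 in liver (exact permutation p = 0.101), which decides neither way. A stronger glucocorticoid response may do so too: without Fkbp5 and Zbtb16 the mean of 8 other responders differed by −0.19 ± 0.19 in liver (exact permutation p = 0.33) and 0.47 ± 0.20 in adipose tissue (exact permutation p = 0.0302, adjusted p = 0.0736 over 39 tests). In liver the members went both ways, Tsc22d3 and Tat at 0.85 and 0.94 and the metallothionein genes Mt1 and Mt2 at −1.24 and −1.91, so the mean there decides nothing. Both explanations and an effect of the sugar itself stay open, and collection times are not given in the sources used here.

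On the second principal component of liver, 12.8% of the variance, ND 7, HFD 1 and ALL 8 lay at −49.45, −42.72 and −50.76. Their nuclear RNA lists (Malat1, Neat1 and others) averaged 3.241, 3.527 and 4.699 log2 CPM, against diet means of 5.92 ± 1.43, 6.01 ± 0.94 and 5.73 ± 0.90, while ND 2 and ALL 4, at 3.689 and 3.9, did not stand apart on that component.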
